A study of Mus musculus with 4 samples.

How the data were processed

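RNA was measured in 4 libraries of mouse 2-cell embryos, 2 control and 2 overexpressing Trim75. Per the labels' protocols, the libraries were built with a transposase-based DNA library kit (TruePrep V2). Per the submitters' processing notes, FastQC, Trim Galore, HISAT2 and featureCounts were used with the mm10 genome. Their versions, the annotation release, and the strand and multi-mapping settings are not given in the sources used here. How genes with near-identical copies, overlapping genes and antisense pairs were counted is therefore unknown, and such genes are reported as uncertain.

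The deposited table gives, per the file headers, a read count and an FPKM value per gene and library, with an Ensembl identifier and a symbol. The counts deposited by the authors are whole numbers that are not normalized, and the lowest sum over the 4 libraries was 2. The FPKM values deposited by the authors equal the count divided by exon length and by a total slightly above the sum of the column (9965512 against 9965081 in control replicate 1), so rows with fewer reads were probably removed before deposit. The lengths implied by the FPKM values matched GENCODE M21 exon lengths within 0.1% for 98.3% of genes in control replicate 1. Of 27115 identifiers, 26680 were found in GENCODE M21 (GRCm38, the same assembly as mm10), which gave positions, exon lengths and GC content, and 435 were not. There were 184 rows with the identifier in place of a symbol and 51 symbols on more than 1 row, and no row lay on the mitochondrial chromosome. With blastn (2.17.0), 16 rows resembled mitochondrial transcripts (at least 90% identity over at least 50% of the transcript).

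Depth ranged from 9965081 to 14599670 reads per library. Genes at 20 reads or more numbered 14059 and 13371 in the control libraries and 15554 and 14982 in the overexpressing libraries. No molecular identifiers are described, so counts include PCR copies and counting error is a lower limit on the error.

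Counts were tested in R (4.3.3) with edgeR (4.0.16). Genes were kept by filterByExpr (16801), scaled by TMM factors and tested with glmQLFit and glmQLFTest on the group, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of the quasi-F statistic. Trim75 was planned as a result of its own and is given with both its own p and the p adjusted over all genes. CPM values are counts scaled to the TMM-adjusted library size. Of 18 gene lists fixed before the data were examined, 17 had tested members, while the list of genes on the mitochondrial chromosome had 0 in the table. Lists were tested two-sided with camera from limma (3.58.1) on log2 CPM (prior count 2) at a preset inter-gene correlation of 0.01, and with camera at an estimated correlation and with fry beside it. camera compares a list with the other genes tested, so higher or lower in this test is relative to those genes. One member each of the TRIM, p53 and histone lists had 0 reads in a whole group, and placing it at the bound of 3 reads over the group left the medians at 0.14, -0.28 and -0.73 and moved the means from 0.21, 0.23 and 0.09 to 0.10, 0.07 and -0.09. A planned Fisher's exact test of list members among changed genes could not be run with 0 edgeR calls, and was run on the DESeq2 calls after the data were seen.

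The named genes were Trim75, then up to 6 higher and 6 lower genes past the adjusted threshold with at least 20 CPM and groups apart, which gave 0 genes, then per list the members past the threshold or, where none passed, the 2 with the highest mean CPM (1 for cumulus and sperm markers). Genes named outside this rule are said to have been chosen after their values were seen.

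Alternatives fixed before the data were examined were other scaling factors (RLE, upper quartile, total counts), no filter or a filter at 5 CPM in 2 libraries, the replicate number as a block, each library left out, Trim75 left out of the library sizes, DESeq2 (1.42.0), limma voom, robust edgeR, limma on log2(FPKM + 1) or log2(FPKM + 0.1), a test against a 1.5-fold change, and list tests without multi-copy families. Leaving out the rows that resemble mitochondrial transcripts with ribosomal RNA rows, the list enrichment among DESeq2 calls, and DESeq2 with each library left out were added after the data were seen. Where a group was left with 1 library, it was assumed to vary like the other group.

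The test was run on counts simulated for the 16801 genes, with 100 genes changed 4-fold and 100 changed 16-fold. At the observed spread (biological coefficient of variation 0.91), the median fitted log2 fold change was 2.00 for the 4-fold and 4.13 for the 16-fold genes. At a coefficient of 0.2, edgeR recovered 95% and 100% of them, with 6 false calls among 201. Figures were drawn with matplotlib (3.10.9) in Python (3.11.15). The study's design text also mentions single-cell data, which were not analysed here.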

Results

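RNA sequencing libraries were made from mouse 2-cell embryos cultured in vitro and collected on day 2. The series had 2 groups of 2 libraries each, control embryos and embryos overexpressing Trim75, a member of the tripartite motif (TRIM) family, many of whose members are E3 ubiquitin ligases. The title of the study names Trim75 as a maternal factor in zygotic genome activation, the start of transcription from the embryo's own genome. The comparison of overexpressing with control embryos therefore asked which transcripts differ when Trim75 is in excess. The deposited table held 27115 genes. The control libraries had 9965081 and 14599670 counted reads, and the overexpressing libraries had 13349188 and 11124411. At least 1 read was seen for 20467 and 19830 genes in the control libraries and for 21886 and 21665 genes in the overexpressing libraries. The labels did not say that the 2 libraries of a group came from separate pools of embryos, so p-values of single genes measure only the spread between these libraries, which may be technical. The list p-values of camera at the preset correlation rest on the spread over genes instead. The titles of the control libraries carried the tag L2C, which those of the overexpressing libraries lacked. If the tag names a stage within the 2-cell stage, the titles gave it for the controls alone. The labels named no batch. The library numbers in the titles fell into 2 separate runs, 1 per group, and a batch that followed these runs could not be told apart from the group.

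Trim75 transcripts were more abundant in both overexpressing libraries than in both control libraries. Trim75 (ENSMUSG00000071089) lies on the minus strand of chromosome 8 from 64980884 to 64987831 (mm10) and is protein coding. Its raw counts were 1773 and 1703 in the control libraries and 12091 and 10537 in the overexpressing libraries. Scaled by library size and TMM factors, Trim75 stood at 144 ± 38.4 CPM (SD, n = 2) in control embryos and 955 ± 49.99 CPM (SD, n = 2) in overexpressing embryos. The log2 fold change was 2.73 ± 0.28 (SE), a 6.64-fold difference. In the edgeR quasi-likelihood test the adjusted p was 0.00043 over this 1 planned gene and 0.32 over all 16801 genes tested. DESeq2 gave Trim75 an adjusted p of 5.2e-14 over all genes. The control libraries also held Trim75 transcripts, so the comparison was between a lower and a higher level.

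The neighbouring genes Trim60 and Trim61, of the same family and on the same strand, also had higher values in both overexpressing libraries, without passing the edgeR threshold. Trim60 (8:64999307 to 65018584) measured 159 ± 0.85 CPM in control and 282 ± 63.1 CPM in overexpressing embryos (SD, n = 2), a log2 fold change of 0.83 ± 0.26 (SE). Trim61 (8:65012987 to 65018523) measured 850 ± 35.3 CPM and 1976 ± 685 CPM (SD, n = 2), a log2 fold change of 1.22 ± 0.30 (SE). The adjusted p in edgeR was 0.37 for Trim60 and 0.32 for Trim61, and in DESeq2 it was 0.15 and 0.013. Trim61 lies inside the span of Trim60 on the same strand, so reads could be assigned to either gene or to neither, and the separate levels are uncertain.

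**Figure D1:**
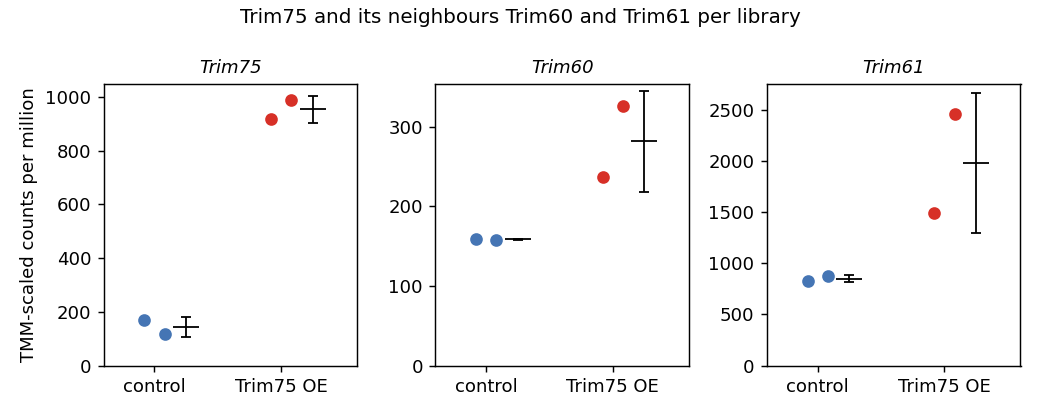
Level of Trim75, Trim60 and Trim61 in each library, in TMM-scaled CPM (vertical axis, from 0), for control (blue points) and Trim75-overexpressing (red points) embryos, with the group mean ± SD in black (n = 2). For Trim75 the control mean was 144 and the overexpressing mean 955, and in all 3 panels both overexpressing libraries lay above both control libraries.

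No gene passed the genome-wide threshold of the main test, yet several abundant transcripts had group means far apart with little spread inside each group. Fmn2, which encodes an actin nucleator needed for spindle positioning in the oocyte, measured 87.4 ± 8.97 CPM in control and 325 ± 17.4 CPM in overexpressing embryos, and Tpd52 measured 546 ± 34.8 and 1485 ± 115 CPM (SD, n = 2). Rgs17, a regulator of G-protein signalling, measured 18.05 ± 0.41 and 143 ± 13.95 CPM, with a log2 fold change of 2.99 ± 0.33 (SE). In the other direction, Arf6, a small GTPase of membrane traffic, measured 800 ± 84.8 CPM in control and 256 ± 14.3 CPM in overexpressing embryos, a log2 fold change of -1.64 ± 0.21 (SE). These genes were chosen after their values were seen, from the 10 with the lowest p, a group that also held Trim75, Pramel27, Ptpre, Ccdc93, Rnf13 and Actr8. The last 5 were close to absent from control embryos: Pramel27 had 7 and 13 reads in the control libraries against 1046 and 698 in the overexpressing ones, and Ptpre had 1 and 2 against 511 and 401.

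With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05, 0 of 16801 genes changed, and the lowest adjusted p was 0.32. At an unadjusted p under 0.05, 1888 genes were counted (11.2%), where 840 would be counted by chance, and of these 1295 were higher and 593 lower in overexpressing embryos. DESeq2 called 885 of 16075 genes, 607 higher and 278 lower. Of the DESeq2 calls, 57 had over 90% of their reads in 1 library. limma on voom weights called 0 genes, with 2169 at an unadjusted p under 0.05. In counts simulated at the observed spread, edgeR recovered 3% of genes changed 4-fold and 43% of genes changed 16-fold with 0 false calls among 46, while DESeq2 recovered 24% and 70% with 241 false calls among 335. The share of false calls depends on how many genes were changed, so it does not carry over to the 885. Chosen after the results were seen, the other splits into pairs gave 187 and 177 DESeq2 calls, and 604 and 544 genes at an unadjusted p under 0.05 in edgeR. In those splits a group difference adds to the spread within pairs. The count at an unadjusted p under 0.05 was 3129 without control replicate 1, 551 without overexpressing replicate 1 and 414 without overexpressing replicate 2, and the DESeq2 count was 2378, 181 and 133 in the same 3 cases. The excess of higher genes under 0.05 was lost with either overexpressing library left out. These fits took their spread from the control libraries alone, and the filter kept 19091 and 19395 genes. Their counts are therefore not directly comparable with those of the main test.

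Ribosomal protein genes were lower, relative to the other genes, in overexpressing embryos in limma's camera test at a preset inter-gene correlation of 0.01 (adjusted p = 2.9e-07 over 17 lists). This call was not kept with an estimated correlation (adjusted p = 0.45). The correlation estimated for this list was 0.0074, below the preset value, so the loss did not come from a higher correlation. The preset form takes its degrees of freedom from the number of genes, so its p does not measure the spread between libraries. The estimated form takes its degrees of freedom from the 4 libraries. The estimates were 0.17 for ribosome biogenesis, 0.039 for oxidative phosphorylation and 0.055 for the spliceosome. Many of these genes have processed pseudogenes of near-identical sequence, so single values are uncertain. Of 83 genes tested, 74 had lower values and 9 higher. Both overexpressing libraries lay under both control libraries in 42 of the 83, and the median log2 fold change was -0.43 (quartiles -0.83 and -0.25). If the 4 libraries were interchangeable, 16.7% of genes would lie so. The share reached among all genes tested is not given here. Counts of genes with the groups apart, in this and the other lists, therefore stand here without that background, and the 16.7% does not replace it. Rplp1, a protein of the ribosomal stalk, measured 275 ± 24.2 CPM in control and 105 ± 24.8 CPM in overexpressing embryos, and Rpl41 measured 240 ± 14.1 and 108 ± 3.49 CPM (SD, n = 2). The 2 most abundant members were Rps27l, at 574 ± 159 and 615 ± 79.5 CPM, and Rpl8, at 480 ± 5.03 and 300 ± 56.8 CPM. The log2 fold change of Rps27l was 0.10, and it turned to -0.17 without control replicate 1 and to -0.04 without overexpressing replicate 2. Ribosomal protein genes took 0.63% and 0.61% of all reads in the control libraries and 0.43% and 0.40% in the overexpressing libraries. DESeq2 called 5 members, all lower (Rplp1, Rpl41, Rps4l, Rps15 and Rps20), named after their values were seen, and edgeR called none over all genes or adjusted over the list alone. Rows that resemble mitochondrial transcripts took 1.35% and 1.598% of reads in the control libraries and 2.13% and 4.01% in the overexpressing libraries, and ribosomal RNA rows took 0.55% and 0.47% against 0.90% and 0.71%.

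Ribosome biogenesis genes, whose products make and process ribosomal RNA in the nucleolus, were lower in the same test (camera adjusted p = 1.8e-05), which gave adjusted p = 0.78 with an estimated correlation. Of 72 genes, 59 had lower values, 31 of them with the groups apart, and the median log2 fold change was -0.55 (quartiles -0.89 and -0.19). Rrp9, a protein of the U3 small nucleolar ribonucleoprotein, measured 354 ± 18.9 CPM in control and 140 ± 11.9 CPM in overexpressing embryos, and Wdr36 measured 250 ± 41.8 and 92.1 ± 15.04 CPM (SD, n = 2). The 2 most abundant members were Wdr43, with a log2 fold change of -0.51 ± 0.22 (SE), and Imp3, with -0.38 ± 0.26 (SE). DESeq2 called 6 members, all lower, and edgeR none over all genes or adjusted over the list alone. The spliceosome list passed as lower relative to the other genes with a camera adjusted p of 0.046, against 0.78 with an estimated correlation. The mean of log2 CPM over this list did not separate the groups, at 5.27 and 5.41 in the control libraries and 5.25 and 5.38 in the overexpressing libraries. In it 44 of 68 genes had lower values, with a median of -0.32 and a mean of -0.11, among them Srsf1 at 542 ± 196 and 338 ± 44.5 CPM, whereas Sf3b1 measured 278 ± 27.99 and 339 ± 44.99 CPM (SD, n = 2). DESeq2 called 1 spliceosome gene, Lsm2, which was lower. Without control replicate 2, the adjusted p in camera was 0.15 for ribosome biogenesis and 0.41 for the spliceosome. fry, which does not compare a list with other genes, gave adjusted p of 0.17, 0.38 and 0.38 for movement in 1 direction in the ribosomal protein, ribosome biogenesis and spliceosome lists, and 0.018, 0.032 and 0.018 for change in either direction. The latter value was also under 0.05 for the other TRIM, interferon response, proteasome, maternal, and pluripotency and lineage lists, which did not pass camera. Rrp9, Wdr36 and Lsm2 were named after their values were seen.

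**Figure D2:**
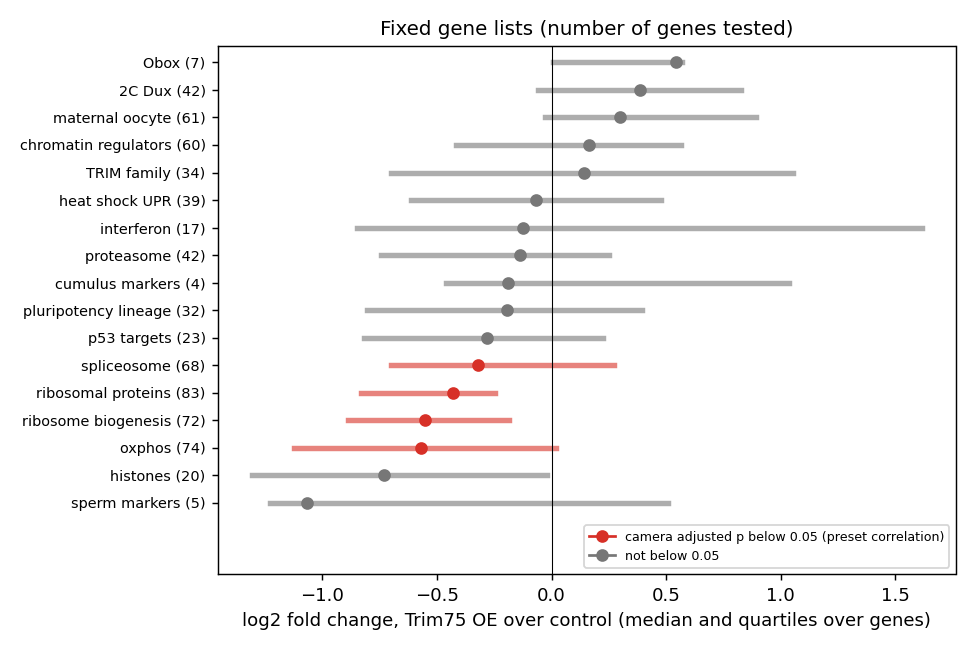
Median (point) and quartiles (bar) of the log2 fold change, overexpressing over control, over the tested genes of each of 17 fixed lists, with the number of genes in parentheses. The lists in red had a camera adjusted p below 0.05 at the preset correlation, a call that none of them kept with an estimated correlation: ribosomal proteins (median -0.43), ribosome biogenesis (-0.55), oxidative phosphorylation (-0.57) and the spliceosome (-0.32).

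Nuclear genes of oxidative phosphorylation were also lower relative to the other genes (camera adjusted p = 0.0016), with adjusted p = 0.77 with an estimated correlation. Of 74 genes tested, 53 had lower values, 27 of them with both overexpressing libraries under both controls, and the median log2 fold change was -0.57 (quartiles -1.12 and 0.02). The mean of log2 CPM over the list overlapped between the groups, at 4.62 and 4.06 in the control libraries and 3.86 and 4.12 in the overexpressing libraries. Ndufa2, a subunit of respiratory complex I, measured 149 ± 8.82 CPM in control and 35.2 ± 1.99 CPM in overexpressing embryos, a log2 fold change of -2.08 ± 0.30 (SE), and Atp5g1, a subunit of the ATP synthase, measured 119 ± 15.02 and 48.1 ± 5.48 CPM (SD, n = 2). They were chosen, as were the members that DESeq2 called, after their values were seen. Of the most abundant members, Cox8a measured 709 ± 100.2 and 522 ± 9.58 CPM, and Atp5b measured 506 ± 179 and 506 ± 52.2 CPM, with no direction that held across settings. The camera adjusted p was 0.16 without control replicate 1. fry gave 0.38 for movement in 1 direction and 0.015 for change in either direction. DESeq2 called 1 member higher (Ndufv3) and 4 lower (Ndufa2, Atp5g1, Ndufs8 and Ndufa8), and in edgeR no member passed over all genes or adjusted over the list alone. The table held no row from the mitochondrial chromosome. The rows that resemble mitochondrial transcripts took 2.13% and 4.01% of reads in the overexpressing libraries against 1.35% and 1.598% in the controls. One of them, Gm29216 on chromosome 1, matches the transcript of cytochrome c oxidase subunit I at 99.8% identity over 483 of its 492 bases, so the source of its reads is uncertain. Gm29216 measured 1245 ± 75.8 and 2608 ± 182 CPM (SD, n = 2). The most abundant of these rows, Gm10925, measured 3860 and 5223 CPM in the control libraries and 6530 and 13570 CPM in the overexpressing libraries. Gm13339 went the other way, at 46.4 ± 0.23 and 35.5 ± 22.9 CPM (SD, n = 2). These rows were named after their values were seen.

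**Figure D3:**
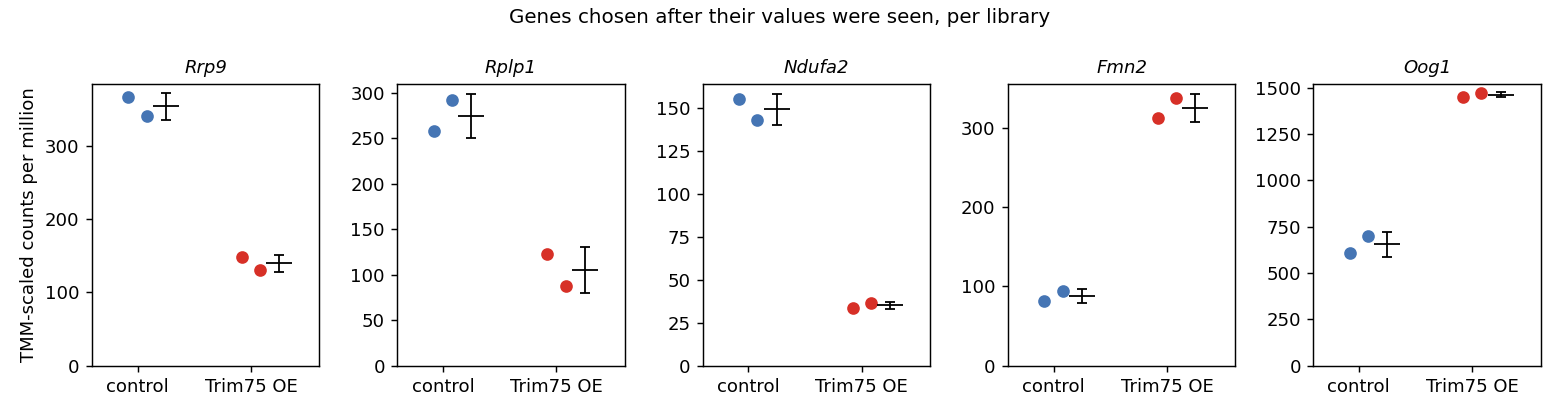
Level per library, in TMM-scaled CPM (vertical axis, from 0), of 5 genes chosen after their values were seen, in control (blue) and Trim75-overexpressing (red) embryos, with the group mean ± SD in black (n = 2). Rrp9, Rplp1 and Ndufa2 were lower in both overexpressing libraries, while Fmn2 and Oog1 were higher, and none passed the genome-wide edgeR threshold.

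The genes that mark the 2-cell stage and are switched on by the transcription factor Dux had mostly higher values in overexpressing embryos, short of the threshold. Of 42 genes tested, 30 were higher and 12 lower, 16 were higher with the groups apart, and the median log2 fold change was 0.39 (quartiles -0.06 and 0.83). The mean of log2 CPM over the list was 5.31 and 5.63 in the control libraries and 6.04 and 6.07 in the overexpressing libraries. The most abundant members were AF067063, at 677 ± 189 CPM in control and 539 ± 5.24 CPM in overexpressing embryos, and Tcstv1, at 341 ± 133 and 426 ± 99.9 CPM (SD, n = 2), a direction that turned without control replicate 1 (log2 fold change -0.04). Zscan4d, named after its values were seen, measured 271 ± 76.8 and 354 ± 43.1 CPM (SD, n = 2). The 1 member that DESeq2 called was Gm4340, at 63.3 ± 6.80 and 184 ± 42.6 CPM (SD, n = 2), and in edgeR no member passed over all genes or adjusted over the list alone. The camera adjusted p was 0.12 at the preset correlation and 0.88 with an estimated correlation, and it fell below the threshold, at 0.0080, without control replicate 2. Many of these genes are near-identical copies in tandem arrays, so reads could be split among them and single values are uncertain. The Obox homeobox genes, which are also multi-copy, had 5 of 7 higher values with a median of 0.54 and a camera adjusted p of 0.88 (0.88 with an estimated correlation). Obox5 measured 1553 ± 354 CPM in control and 2265 ± 709 CPM in overexpressing embryos, and Obox1 measured 493 ± 79.1 and 642 ± 266 CPM (SD, n = 2), with a log2 fold change of 0.38 that turned to -0.12 without overexpressing replicate 2.

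Transcripts stored in the oocyte had mostly higher values in overexpressing embryos, also short of the threshold. Of 61 maternal genes tested, 45 had higher values, 27 of them with the groups apart, and the median log2 fold change was 0.30 (quartiles -0.03 and 0.89). Spin1, a spindle-associated chromatin reader, measured 3564 ± 101 CPM in control and 5277 ± 135 CPM in overexpressing embryos, a log2 fold change of 0.57 ± 0.16 (SE), while Btg4, an adaptor for maternal mRNA decay, measured 4860 ± 894 and 5341 ± 1300 CPM (SD, n = 2). The log2 fold change of Btg4, 0.14, turned to -0.05 without control replicate 1 and to -0.14 without overexpressing replicate 2. DESeq2 called 7 members higher and 1 lower. Oog1 measured 655 ± 66.5 and 1462 ± 15.05 CPM, Cnot6l, a catalytic subunit of the CCR4-NOT deadenylase, measured 218 ± 43.3 and 639 ± 139 CPM, and Nlrp4f measured 489 ± 1.37 and 998 ± 195 CPM (SD, n = 2). The member called lower was H1f8, the linker histone of the oocyte, at 669 ± 17.6 and 258 ± 12.3 CPM (SD, n = 2). These last 4 genes were chosen after their values were seen. The camera adjusted p of the list was 0.26 at the preset correlation and 0.88 with an estimated correlation, fry gave 0.38 for movement in 1 direction and 0.049 for change in either direction, and no member passed in edgeR over all genes or adjusted over the list alone.

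The proteasome list had members that went both ways. Psme4, an activator of the proteasome, measured 554 ± 15.1 CPM in control and 1035 ± 47.7 CPM in overexpressing embryos, a log2 fold change of 0.90 ± 0.19 (SE), and Psmd3 measured 388 ± 0.42 and 293 ± 43.0 CPM (SD, n = 2). Psmc4 and Psmb10, named after their values were seen, had log2 fold changes of -2.003 ± 0.43 and -2.82 ± 0.66 (SE). DESeq2 called Psme4, Psmc4 and Psmb10, and edgeR called no member over all genes or adjusted over the list alone. Over its 42 genes the median was -0.14 and the camera adjusted p 0.085, or 0.77 with an estimated correlation, while fry gave 0.38 for movement in 1 direction and 0.015 for change in either direction.

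Of 56 histone genes in the table, 20 passed the count filter. Of these, 15 had lower values, with a median log2 fold change of -0.73 and a mean of -0.09 with H1f1, which had 0 control reads, at the bound of 3 reads over the group. The mean of log2 CPM over the list overlapped between the groups, at 1.86 and 0.75 in the control libraries and 0.78 and 1.40 in the overexpressing libraries. The mean of the fitted values, 0.09, was -0.38 without H1f1, and H4c9 also raised it, with a log2 fold change of 7.45. H2ac23 measured 101 ± 21.5 CPM in control and 35.1 ± 16.6 CPM in overexpressing embryos, and H2ac24 measured 99.5 ± 24.5 and 35.6 ± 15.3 CPM (SD, n = 2). Copies of a histone gene share sequence, so their separate levels are uncertain. The camera adjusted p was 0.068, or 0.83 with an estimated correlation. DESeq2 called H1f1 and H4c9 higher, and H4c9 had at most 1 read per control library. H1f1, H4c9 and Perp were named after their values were seen. The p53 target Gadd45a measured 324 ± 168 and 112 ± 38.8 CPM (SD, n = 2), and the other named member of that list, Tigar, measured 224 ± 48.5 and 184 ± 3.33 CPM (SD, n = 2). Over 23 p53 targets the median was -0.28, with an adjusted p in camera of 0.62 (0.88 with an estimated correlation) toward lower. The sign of the mean rested on Perp, which had 0 control reads, at 0.07 with Perp at its bound and -0.15 without it.

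Among 32 pluripotency and lineage genes the median log2 fold change was -0.19 and the camera adjusted p 0.37, and fry gave 0.66 for movement in 1 direction and 0.049 for change in either direction. Klf17 measured 987 ± 41.2 CPM in control and 874 ± 127 CPM in overexpressing embryos, and Klf4 measured 498 ± 7.55 and 442 ± 189 CPM (SD, n = 2), differences smaller than or close to the spread within groups, and Klf4 had a log2 fold change of 0.21 without overexpressing replicate 2. Among 60 chromatin regulators the median was 0.16 and the adjusted p in camera 0.88, toward lower relative to the other genes. fry, which makes no such comparison, pointed to higher, as did the median (adjusted p = 0.38). H3f3b, a replication-independent histone H3, measured 866 ± 164 and 1344 ± 323 CPM, and Ezh2, the methyltransferase of Polycomb repressive complex 2, measured 936 ± 40.4 and 1262 ± 136 CPM (SD, n = 2). Heat shock and unfolded protein response genes (39 tested) had a median of -0.07 and an adjusted p of 0.88 in camera. Atf4, a transcription factor of the integrated stress response, measured 873 ± 98.0 and 567 ± 14.3 CPM, and Hsp90ab1 measured 512 ± 94.1 and 423 ± 43.4 CPM (SD, n = 2). In these 3 lists DESeq2 called 0, 1 (Rnf2) and 1 (Eif2ak3) members, the latter 2 higher and named after their values were seen, and edgeR called none.

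Interferon response genes had a median log2 fold change of -0.12 and a mean of 0.69 over 17 tested members. The adjusted p in camera was 0.88 toward higher relative to the other genes, a sign that the mean shared and the median did not. The 2 most abundant, Ifitm3 and Irf9, varied between libraries of 1 group: Ifitm3 measured 28.6 ± 9.67 and 48.7 ± 34.5 CPM, and Irf9 measured 59.9 ± 84.5 and 14.7 ± 7.54 CPM (SD, n = 2), with 1 read in control replicate 1. The log2 fold change of Ifitm3, 0.77, was -0.23 without overexpressing replicate 2, and that of Irf9, -2.03, was 7.09 without control replicate 2. Other TRIM genes (34 tested, Trim75 left out) had a median of 0.14 and an adjusted p in camera of 0.89 toward lower relative to the other genes. fry pointed to higher, as did the median. Their mean was 0.10 with Trim40, which had 0 control reads, at its bound and -0.07 without it. Of the 34, DESeq2 called 3 higher (Trim61, Trim13 and Trim40) and 1 lower. Outside the edgeR filter it also called Trim30a higher, which had 370 reads in overexpressing replicate 2 and 0 in the other 3 libraries. The member called lower was Trim65, which like Trim13, Trim40 and Trim30a was named after the values were seen, at 32.7 ± 0.79 and 0.51 ± 0.08 CPM (SD, n = 2). Of the lists of markers of other cells, 4 of 15 cumulus cell genes and 5 of 8 sperm genes in the table passed the count filter. Their adjusted p in camera was 0.89 and 0.88. Whether the reads came from such cells was not tested. Amhr2, the most abundant member of the cumulus list, measured 48.2 ± 12.2 CPM in control and 34.2 ± 8.87 CPM in overexpressing embryos, and Odf2, the most abundant member of the sperm list, measured 296 ± 50.8 and 439 ± 50.7 CPM (SD, n = 2). Over the cumulus genes the median was -0.19 and the mean 0.76, with the test toward lower, and over the sperm genes the median was -1.07. With an estimated correlation these 4 lists had adjusted p between 0.88 and 0.89. fry for change in either direction gave 0.015 for the interferon response and 0.0078 for the other TRIM genes, against 0.38 and 0.38 for movement in 1 direction.

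The control libraries were about as far from each other as from the overexpressing libraries, while the overexpressing libraries were closer to each other. The median absolute difference in log2 CPM was 0.86 between the control libraries, 0.65 between the overexpressing libraries and between 0.85 and 1.00 across groups. Across genes, Pearson's r of log2 CPM was 0.70 between the control libraries, 0.81 between the overexpressing libraries and between 0.70 and 0.73 across groups, and genes are not independent replicates. The biological coefficient of variation in edgeR was 0.91. No 2 libraries were copies of each other, since replicate counts differed by a chi-square of 118 per degree of freedom in control and 69.7 in overexpressing embryos.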

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

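DESeq2 with each library left out was chosen after the data were seen, as was leaving out the rows like mitochondrial transcripts. The Trim75 log2 fold change kept its direction, and its p as 1 planned gene stayed under 0.05, under all alternatives that held the gene, from 2.48 without control replicate 2 to 3.02 without control replicate 1. Adjusted over all genes, its p was 0.32 in edgeR and 5.2e-14 in DESeq2. The count of changed genes was 0 in all alternatives except DESeq2, which gave 885. The count at an unadjusted p under 0.05 was 1198 with the filter at 5 CPM, which tested fewer genes, and ranged from 414 without overexpressing replicate 2 (551 without overexpressing replicate 1) to 3129 without control replicate 1. The DESeq2 count ranged from 133 to 2378 over the same fits. Higher genes made up 68.6% of those under 0.05, 55.7% on log2(FPKM + 1), and 49.0% and 47.3% without overexpressing replicate 1 or 2, so that the majority turned to lower with either of these libraries left out. The median log2 fold change of all genes was 0.03, and 0.37 and 0.21 without control replicate 1 or 2, 0.15 with voom and 0.14 with the replicate block, and it turned to -0.07 and -0.05 without overexpressing replicate 1 or 2 and to -0.04 with total counts. With a library left out, the filter kept a different and larger set of genes.

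Of 4 lists that passed camera, 0 passed with an estimated correlation and 0 with fry for movement in 1 direction, while all 4 passed fry for change in either direction (adjusted p from 0.015 to 0.032). The adjusted p with an estimated correlation and with fry for 1 direction was 0.45 and 0.17 for ribosomal proteins, 0.78 and 0.38 for ribosome biogenesis, 0.77 and 0.38 for oxidative phosphorylation, and 0.78 and 0.38 for the spliceosome. Leaving out 1 library, the adjusted p in camera ranged from 8.7e-08 to 7.4e-05 for ribosomal proteins, from 3.3e-07 to 0.15 for ribosome biogenesis (the highest without control replicate 2), from 0.00016 to 0.16 for oxidative phosphorylation (the highest without control replicate 1), from 0.0099 to 0.41 for the spliceosome (the highest without control replicate 2) and from 0.0080 to 0.93 for the Dux genes. The spliceosome list also lost its call with upper-quartile factors (0.051) and with the replicate block (0.098). The direction of the 4 lists was the same in all 15 alternatives. The cause of these differences was not tested.

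The replicate numbers pair nothing that the labels name, and the deviations of same-numbered libraries correlated at 0.01. With the replicate block, Trim75 had a log2 fold change of 2.75, 0 genes changed and 1342 had an unadjusted p under 0.05. The block changed no call other than that of the spliceosome. Among the named genes, 8 reversed under some alternative, none of them called. Atp5b, at 0.00, was -0.0070 with RLE factors, -0.059 with total counts, -0.0086 with no filter, -0.0042 with the filter at 5 CPM, -0.0049 without the rows like mitochondrial transcripts, -0.0081 in DESeq2, and -0.027 in all 3 FPKM fits. Irf9, at -2.03, was 1.13 with the replicate block, 0.98 with voom and 0.66 on log2(FPKM + 0.1). Leaving out 1 library, log2 fold changes ranged from -0.33 to 0.41 for Atp5b, -3.04 to 7.09 for Irf9, -0.042 to 0.78 for Tcstv1, -0.12 to 0.73 for Obox1, -0.17 to 0.41 for Rps27l, -0.14 to 0.34 for Btg4, -0.71 to 0.21 for Klf4 and -0.23 to 1.33 for Ifitm3.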

Other observations

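The tests of library batch, developmental stage, reads shared with Trim75, genes captured and other splits were chosen after the results were seen, as were the genes named in this part.

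Some genes were seen in both libraries of 1 group and close to absent from the other. With at least 10 CPM in both libraries of a group and at most 0.5 CPM in both of the other, 80 genes were seen in overexpressing embryos alone and 10 in control embryos alone. Il34, a cytokine, had 597 and 267 reads in the overexpressing libraries and 0 in both controls, and Aass, an enzyme of lysine breakdown, had 483 and 261 against 0. In the other direction, Smc2, a condensin subunit, had 145 and 350 reads in control and 0 and 2 in overexpressing embryos, and Ahr, the aryl hydrocarbon receptor, had 181 and 351 against 0 and 2.

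Eif2ak2, Oas1b and Ddx58, which sense double-stranded RNA, were among the genes that DESeq2 called higher in overexpressing embryos. Their interferon response list had 7 higher and 10 lower values among the 17 members tested in edgeR. Eif2ak2 had 0 and 1 reads in the control libraries against 103 and 51, Oas1b had 1 and 1 against 94 and 43, and Ddx58 had 32 and 1 against 238 and 570. These 3 of 21 interferon response genes compared with 0.79 expected among the DESeq2 calls (Fisher's exact test, adjusted p = 0.29 over 34 tests of list and direction), which missed the threshold. In the same family of tests the lowest adjusted p was 0.052, for 6 ribosome biogenesis genes called lower where 1.25 were expected. Whether fewer genes captured in the control libraries, described below, gave the low control counts of Eif2ak2 and Oas1b was not tested.

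Ribosomal protein, ribosome biogenesis and oxidative phosphorylation genes had medians of -0.43, -0.55 and -0.57 on the log2 scale. In 10000 random lists matched on mean expression, exon length and GC content, the median was -0.20, -0.03 and -0.12. The 2.5th percentile was -0.42, -0.24 and -0.37, and all 3 lists lay below it, ribosomal proteins narrowly, at percentile 1.87. A trend with these properties thus gave smaller shifts on average. The genes of a random list were drawn independently, whereas list members can vary together. The percentiles are therefore too narrow to exclude such a trend as the whole cause. A library batch, which the labels do not name, stays open: 0 of 2 runs of library numbers held both groups, so a batch that followed them cannot be told apart from Trim75. An earlier stage of the overexpressing embryos may also lower these genes. The maternal list, taken as its test after the list results were seen, had a camera adjusted p of 0.26 toward higher, which decides neither way. An effect of Trim75 itself stays among the open explanations, untested.

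Trim60 and Trim61 had higher values beside Trim75. Reads shared with the overexpressed transcript are a candidate explanation that the sequences argue against, since 0 stretches of 50 bases of Trim60 or Trim61 transcripts occur in Trim75 transcripts. For a rise of the whole neighbourhood, the other 6 tested genes within 1 Mb had a median log2 fold change of 0.22, from -0.88 to 2.71. This lay below the 0.83 of Trim60 by less than their interquartile range of 1.56. With so wide a range the rule could not have rejected even a flat neighbourhood, so that explanation stays undecided. The genes went both ways: Tmem192 (-0.30), Cpe (-0.68) and Msmo1 (-0.88) were lower, and Gm45445 (0.73), Tll1 (1.06) and Klhl2 (2.71) higher. Klhl2 had 78 and 0 control reads. Library batch and an effect of Trim75 also stay open.

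The excess of genes seen only in overexpressing embryos, 80 against 10, may follow in part from fewer genes being captured in the control libraries. Genes at 10 CPM or more in 1 library of a group and at most 0.5 CPM in the other numbered 719 and 350 in control and 118 and 110 in overexpressing embryos, so that the lowest control count exceeded the highest overexpressing count by 232, as that explanation needs. If each control library lost genes independently, at a rate set by expression level, 20.4 of the 8511 genes at 10 CPM or more in both overexpressing libraries would be missed by both (up to 30 within Poisson counting error), which argues against such losses as the whole cause of the 80. Of the 3 splits of the 4 libraries into pairs, 1 (the real one) gave as many genes in 1 pair alone and the highest other split gave 28, and with 3 splits the share cannot fall under 0.05. Losses that strike the same genes in both control libraries, control embryos that differ more from each other, and a response to Trim75 stay open, the last untested.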
